A study of Homo sapiens with 12 samples.

How the data were processed

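RNA immunoprecipitation followed by sequencing was analysed in 12 libraries from established breast cancer cell lines. MCF-7 is an estrogen receptor positive line and MDA-MB-231 is an estrogen receptor negative line. MCF-7 cells had received vehicle or 17β-estradiol (E2) at 10 nM for 12 h, and MDA-MB-231 cells formed the other culture. Each of the 3 cultures gave 4 libraries: the input RNA of the lysate, RNA recovered with a control IgG, RNA recovered with an antibody against PSF (the protein of the SFPQ gene) and RNA recovered with an antibody against NONO. Each culture and fraction had 1 library, so there were no replicates. Per the labels, the sequencing libraries were made with an RNA target enrichment kit, and its target regions are not given in the sources used here.

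Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with Bowtie2 2.2.6 and TopHat2 2.1.0 to the human genome build hg19, and counted on RefSeq transcripts. The Trimmomatic version, the program that counted reads and the strand setting are not given in the sources used here. The deposited files label each count as unique. Beyond that label, the treatment of reads that map to several places is not given there. The files deposited by the authors list the read count of each transcript with at least 1 read, so a transcript absent from a file was taken as a count of 0. The same deposited files give a signal (the rpm column, reads scaled to the library), which the authors made from the count and the mapped total of the library. They also give RPKM values, which the authors made from that signal and the transcript length, and both columns were recomputed from the counts without a difference. Mapped reads per library ranged from 3199311 to 32229130. Only the counts were used, since the derived columns hold no further measurement. Each transcript is counted on its own in these files, so a read shared by several transcripts of a gene is counted for each of them.

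The files held 55994 transcripts, of which 55751 (99.57%) received a gene symbol and 243 did not. These formed 20472 genes, of which 9676 had 1 transcript, and 154 transcript identifiers stood at more than 1 position. The transcript with the highest mean count over the 12 libraries stood for its gene. Counts without a symbol took between 0.0918% and 0.27% of a library. Gene names came from a RefSeq gene annotation, and from GENCODE 29 for transcript identifiers absent there. Coding lengths and GC content came from GENCODE 29, which is on a later genome build. Positions printed here are therefore those of the deposited files on hg19.

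The tested comparisons used the edgeR 4.0.16 quasi-likelihood test with TMM normalization and the filterByExpr filter, which left 13832 genes. The model held fraction and culture, with 6 residual degrees of freedom, and the threshold was a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. TMM factors lay between 0.8106 and 1.1686. The cultures stood in for replicates of an antibody effect common to them, and 2 of the 3 cultures were the same cell line, so p-values measure spread between these cultures and not between repeated experiments. Errors printed after ± are standard errors of the fitted log2 fold change over 3 cultures. A further model with a term for cell line by fraction, with 3 residual degrees of freedom, tested whether a ratio differed between MDA-MB-231 and the MCF-7 cultures, and its spread came from the pair of MCF-7 cultures alone. The comparisons of E2 with vehicle and of MDA-MB-231 with MCF-7 rested on 1 library per side and had no test. Their values are log2 ratios of TMM-normalised counts with a pseudocount of 0.5, with exact 95% counting intervals from the binomial distribution. Shares of counts carry 95% Wilson intervals. A gene at 0 on one side received a lower bound on its fold, computed against a floor of 3 counts per library. These intervals and floors cover counting error only.

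The following were fixed before the data were examined: the comparisons, the tests, most alternatives, 20 gene lists and the rule for named genes. For PSF or NONO against IgG the rule took the 10 highest and 5 lowest fitted changes among genes past the threshold with the same sign in all 3 cultures, and for PSF against NONO the 5 highest and 5 lowest. For E2 it took the 10 highest and 10 lowest input ratios among genes with 50 counts in 1 of the input libraries and the same direction in all 4 fractions. For recovery under E2 it took the 5 highest and 5 lowest differences per antibody, among genes past the threshold with 50 counts in each MCF-7 IgG, PSF and NONO library. For the cell lines it took the 5 highest and 5 lowest input ratios among genes with 50 counts on one side. In each comparison it added the study genes and the 2 to 4 members of each list with the largest change. Small RNA genes under 200 bases were counted as a class.

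The 20 lists were study genes named in publications on PSF and NONO in breast cancer (possibly chosen on these libraries), bait protein mRNAs, paraspeckle proteins, nuclear-retained long non-coding RNAs, snoRNA host genes, structured small non-coding RNAs, snoRNAs and scaRNAs, replication-dependent histones, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, C2H2 zinc finger (ZNF) genes, estrogen-induced genes, estrogen-repressed genes, luminal epithelial markers, mesenchymal markers, S phase and mitosis genes, SCF ubiquitin ligase and cell cycle inhibitors, circadian clock genes, vesicle transport genes of the SCFD2 group, and blood, fibroblast and liver markers as a check for other cell types. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. For the comparisons without a test, the median of each list was placed among 10000 random lists matched on expression in 20 bins.

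The alternatives were DESeq2 size factors, total counts alone, other filters on low counts (none beyond 1 count, or a mean of 50), the DESeq2 1.42.0 Wald test, a fit of the 6 libraries of each comparison, each culture left out, counts summed over transcripts, input in place of IgG, a pseudocount of 5 and a filter of 10 counts. Each library left out in turn, the same alternatives for the comparisons with input, the lists without the MDA-MB-231 IgG library, the nuclear-retained list without SLC7A2, and random lists matched on expression and transcript length were added after seeing the data. Every split of the 6 libraries of a comparison into 3 and 3 was also fitted, which gives 10 splits.

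The tests were tested on simulated data with the dispersions of these libraries and 100 changed genes per size. At a true log2 change of 2, edgeR recovered 76% of changed genes for PSF against IgG, 80% for NONO against IgG, 84% for PSF against NONO, 76% for PSF against input, 76% for NONO against input and 78% for IgG against input. At a true log2 change of 1 these shares were 16%, 18%, 10%, 10%, 5% and 13%, so smaller changes were mostly missed. False calls numbered 5, 6, 20, 3, 7 and 7 in the same order. DESeq2 recovered 33% and 81% for PSF against IgG, with 18 false calls. The test of a difference between lines recovered 43% and 72%, with 9 false calls. List percentiles were checked on other simulated values, drawn independently for each gene, with lists of 25 random genes. Of 100 unchanged random lists, 4 fell outside the central 95%, and 20 of 20 shifted lists were recovered. Correlation between the members of a list was not simulated. Calculations ran in R 4.3.3 and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

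No library was left out. The input library of MCF-7 cells given vehicle carries a label that names it both MCF-7 and estrogen receptor negative. ESR1, the estrogen receptor gene, had 617 counts in that library and 0 in the MDA-MB-231 input, and the library was kept as MCF-7.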

Results

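The libraries measured RNA recovered with antibodies against PSF and NONO. These are a pair of nuclear proteins that bind RNA and DNA and form paraspeckles with the long non-coding RNA NEAT1. RNA was recovered from lysates with an antibody against each protein or with a control IgG, and the input RNA was sequenced beside it. The 12 libraries came from 3 cultures: MCF-7 given vehicle, MCF-7 given E2, and MDA-MB-231. Each culture and fraction had 1 library. In MCF-7 given vehicle the counts over genes were 1570129 for input, 2561914 for IgG, 4266915 for PSF and 13354097 for NONO. In MCF-7 given E2 they were 2311323 for input, 2432200 for IgG, 7892226 for PSF and 11392006 for NONO. In MDA-MB-231 they were 4522408 for input, 6000550 for IgG, 24054811 for PSF and 11206981 for NONO. Between 13706 and 17678 genes were detected per library.

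The RNAs that filled the libraries differed by fraction. RNA of the mitochondrial genome, which is made and kept inside mitochondria, took 38.5% of input counts in MDA-MB-231 (95% Wilson interval 38.5% to 38.6%), and 5.81% of PSF and 0.328% of NONO counts. In MCF-7 given vehicle these shares were 26.8% of input, 4.28% of PSF and 0.523% of NONO counts, and in MCF-7 given E2 they were 46.3%, 4.46% and 0.655%. MALAT1, a long non-coding RNA of nuclear speckles, took 4.91% of PSF counts in MDA-MB-231 against 0.515% of input, and 4.03% of IgG counts. NEAT1, the scaffold of paraspeckles, took 0.424% of IgG counts in MDA-MB-231 and 0.0631% of PSF counts. The mRNAs of cytosolic ribosomal proteins took 3.28% of input counts and 0.599% of NONO counts in MCF-7 given vehicle.

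**Figure D1:**
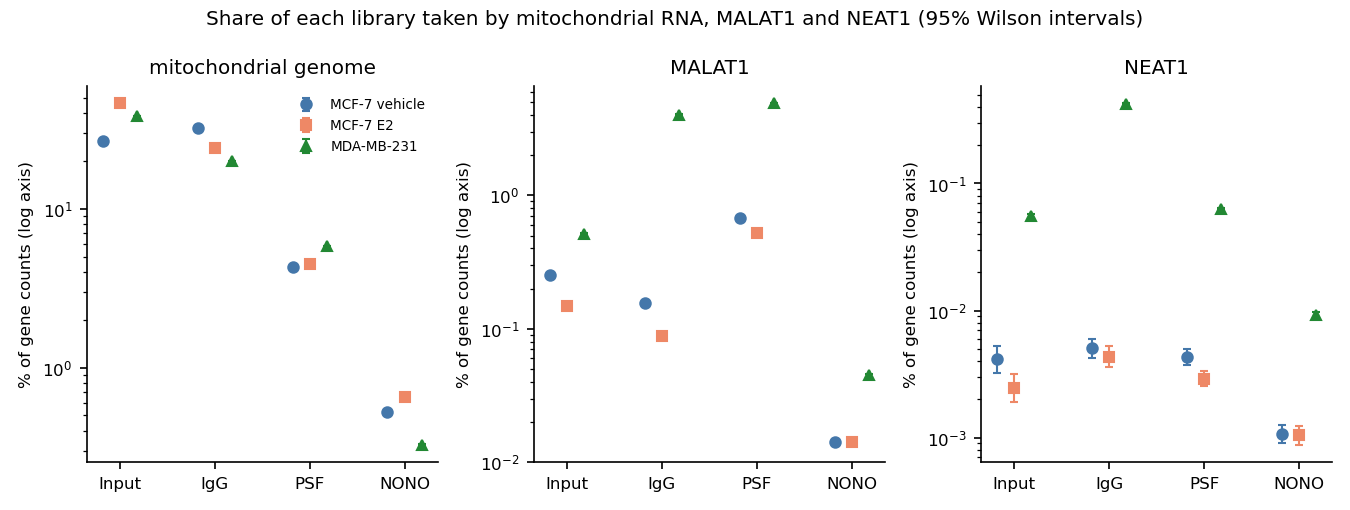
The panels plot the percentage of gene counts (log axis) taken by mitochondrial RNA, MALAT1 and NEAT1 in input, IgG, PSF and NONO libraries, with 1 point per library, a symbol per culture and 95% Wilson intervals. Mitochondrial RNA took at most 0.655% of NONO counts, and the NEAT1 share of MDA-MB-231 IgG (0.424%) was the highest of the 12 libraries.

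PSF against IgG asked which RNAs were recovered with PSF beyond the background of the control antibody. Genes of mitosis were among the 10 highest with PSF. TOP2A (NM_001067, chromosome 17, 38544773 to 38574202 of hg19), the topoisomerase that untangles DNA before division, was recovered 6.83-fold more (log2 2.77 ± 0.52, adjusted p 0.00349). CENPE (NM_001813, chromosome 4, 104026963 to 104119566), a kinesin of the kinetochore, was recovered 6.46-fold more (2.69 ± 0.57). HMMR (NM_001142556, chromosome 5, 162887517 to 162918953) and TPX2 (NM_012112, chromosome 20, 30326904 to 30389603), which act on the spindle, were recovered 6.39-fold and 5.84-fold more (2.67 ± 0.52 and 2.54 ± 0.51). RYR1 (NM_000540, chromosome 19, 38924340 to 39078204), a calcium channel with a very long mRNA, was recovered 7.37-fold more (2.88 ± 0.49), and SPTAN1 (NM_001363759, chromosome 9, 131314866 to 131395938), a spectrin, 5.86-fold more (2.55 ± 0.46). TCHH (NM_007113, chromosome 1, 152078793 to 152087930), a hair follicle protein, had 171 counts with PSF and 3 with IgG over the cultures, a ratio of 18.4 with a 95% counting interval from 6.21 to 90.3. COL28A1, a collagen gene, had 30 PSF counts and 0 IgG counts, at least 1.08-fold more, and ANKRD30A and FAM184B had pooled ratios of 10.9 and 11.8. With input as the control COL28A1 (adjusted p 0.11) and FAM184B (0.93, adjusted p 0.254) did not pass. The log2 ratio of TOP2A was 1.05 in MDA-MB-231, 4.12 in MCF-7 given vehicle and 3.90 in MCF-7 given E2. Without the vehicle culture or without the E2 culture 0 genes passed upward in edgeR, and TOP2A stood at 2.19 (adjusted p 0.146) and 2.26 (adjusted p 0.113).

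Structured non-coding RNAs were among the lowest with PSF. RPPH1 (NR_002312, chromosome 14, 20811230 to 20811570), the RNA of ribonuclease P, was 17.0-fold lower with PSF than with IgG (log2 −4.08 ± 0.31, adjusted p 8.38e-05). RN7SL3 (NR_145670, chromosome 14, 50320334 to 50320632), a signal recognition particle RNA, was 24.0-fold lower (−4.58 ± 0.44), and SNORD133 (NR_132753, chromosome 12, 50850354 to 50850569), a small nucleolar RNA, 21.4-fold lower (−4.42 ± 0.34). CLPSL2, which had 16 IgG counts and 1 PSF count, and GNG13, which had 7 and 1, completed the 5 lowest, with ratios of 49.5 (7.68 to 2074) and 21.6 (2.78 to 975), and the CLPSL2 call was lost without the vehicle culture (0.195) and the GNG13 call with no filter (0.106) and with counts summed over transcripts (0.0621). Of 13832 genes, 1873 were higher and 1610 lower with PSF, 5322 had an unadjusted edgeR p under 0.05, and 3373 of the called genes had the same sign in all 3 cultures. Over 4-fold, 58 genes were higher and 173 lower. Few calls remained when an MCF-7 culture was left out: 0 genes were higher and 37 lower without the vehicle culture, and 0 and 53 without the E2 culture. Without MDA-MB-231 3832 were higher and 3714 lower. RPPH1, RN7SL3 and SNORD133 passed in each of these fits. Counts fell to 754 higher and 731 lower without the vehicle IgG library, 701 and 763 without the vehicle PSF library, 855 and 907 without the E2 IgG library, and 658 and 791 without the E2 PSF library.

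The study genes, named in publications on PSF and NONO, were read for recovery with PSF, as were the mRNAs of the bait proteins and PSPC1. ESR1 (NM_001122742, chromosome 6, 152011631 to 152424408), which encodes the estrogen receptor, was not separated from IgG (log2 −0.26 ± 0.34, adjusted p 0.600), but passed as lower without the MDA-MB-231 culture (−0.33, adjusted p 0.0017). SCFD2 (NM_152540, chromosome 4, 53739151 to 54232242), which belongs to a family of vesicle transport proteins, had a log2 ratio of 0.98 ± 0.43 (adjusted p 0.110) and passed the threshold without the MDA-MB-231 PSF library (1.42, adjusted p 0.0354) or culture (1.49, adjusted p 0.00138). SKP2 (NM_005983, chromosome 5, 36152145 to 36184142), which directs cell cycle inhibitors to degradation, was 1.96-fold lower with PSF (−0.97 ± 0.27, adjusted p 0.0222). The SKP2 call was lost without any one of the MCF-7 IgG and PSF libraries (adjusted p 0.0799 to 0.105). E2F8 (NM_024680, chromosome 11, 19245610 to 19262507), a repressor of the E2F family, had 0.28 ± 0.25 (adjusted p 0.437). SFPQ (NM_005066, chromosome 1, 35649201 to 35658743), the mRNA of PSF itself, had 1.43 ± 0.61 (adjusted p 0.108), with 0.04 in MDA-MB-231, 2.55 in MCF-7 given vehicle and 2.99 in MCF-7 given E2. Without the MDA-MB-231 IgG library SFPQ stood at 2.93 (adjusted p 3.85e-05) and NONO mRNA at 1.37 (adjusted p 0.0321), against 0.56 ± 0.47 for NONO mRNA with it. PSPC1 (NR_149052, chromosome 13, 20248892 to 20357176), the third member of the protein family, was 3.04-fold higher (1.60 ± 0.53, adjusted p 0.0424), a call lost without any one of 7 libraries (adjusted p 0.0521 to 0.198), with a mean count of 50 (0.0547) or with counts summed over transcripts (0.0654).

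**Figure D2:**
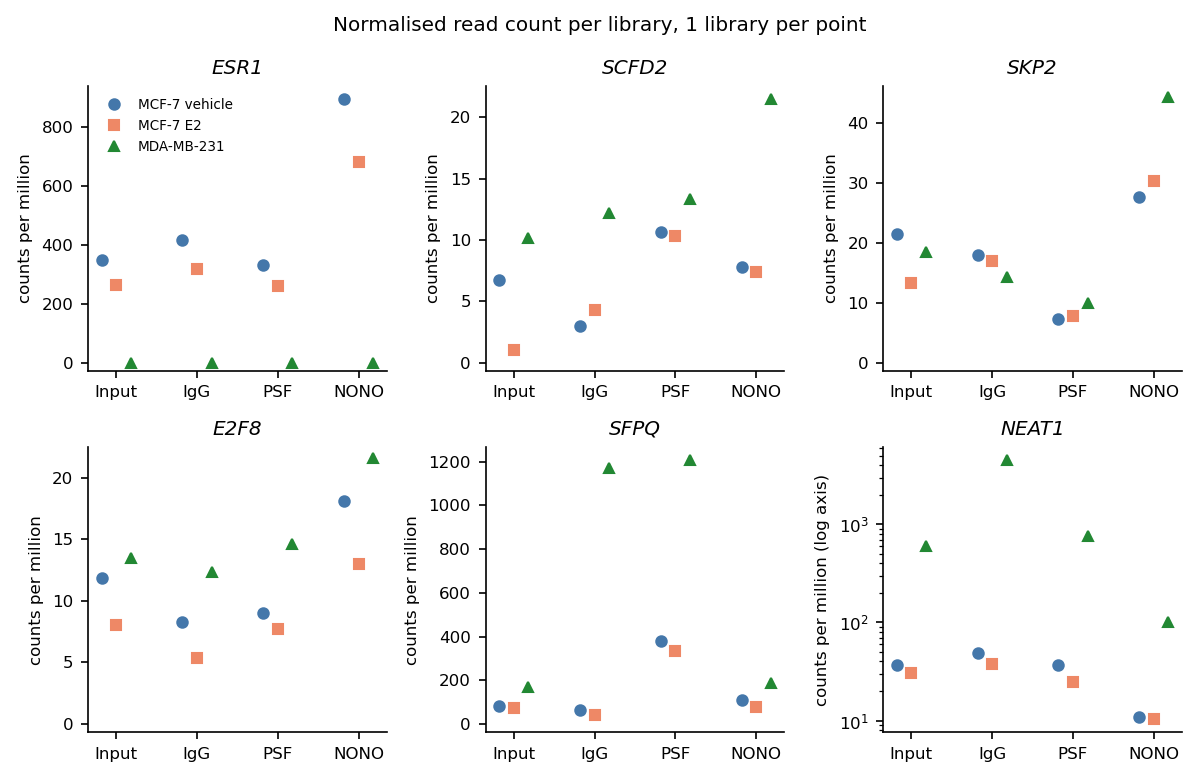
Each panel plots the normalised read count of a gene (y axis in CPM, log axis for NEAT1) in input, IgG, PSF and NONO libraries, with 1 point per library and a symbol per culture. SFPQ was 7.04-fold over input with PSF and 6.84-fold over input with IgG in MDA-MB-231.

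Among the lists, genes of S phase and mitosis were recovered more with PSF, and short housekeeping mRNAs less. Of 34 genes of S phase and mitosis 15 were higher and 3 lower (17 and 3 adjusted over the list alone), with a median of 0.77 (camera adjusted p 0.00168, 0.395 with estimated correlation). PLK1, a mitotic kinase, was 3.56-fold higher (1.83 ± 0.32), and MCM10, a replication factor, 3.47-fold (1.80 ± 0.31). Of 27 paraspeckle protein genes 7 were higher and 2 lower (8 and 2 adjusted over the list alone; median 0.50, adjusted p 0.0448, 0.517 estimated). FUS, which binds RNA and carries variants in motor neuron disease, was 2.56-fold higher (1.36 ± 0.27), and RBM7, a factor that guides RNA decay, 3.14-fold lower (−1.65 ± 0.31). Of 12 vesicle transport genes 5 were higher and 0 lower over all genes and over the list alone (median 0.68, adjusted p 0.016, 0.202 estimated). Without an MCF-7 culture the paraspeckle list did not pass (adjusted p 0.087 to 0.095), nor did the vesicle list without MDA-MB-231 (0.114), and the calls of PLK1, MCM10, FUS and RBM7 were lost without either MCF-7 culture.

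Of 78 ribosomal protein genes 0 were higher and 49 lower with PSF (1 and 57 adjusted over the list alone), with a median of −1.19 (adjusted p 7.86e-17, 0.202 estimated). RPS13, a protein of the small subunit, was 6.55-fold lower (−2.71 ± 0.30). Of 87 nuclear-encoded respiratory chain genes 3 were higher and 49 lower (3 and 56 adjusted over the list alone; median −1.10, adjusted p 5.05e-14, 0.204 estimated), and COX6C, a cytochrome oxidase subunit, was 5.43-fold lower (−2.44 ± 0.33). Of 57 histone genes 2 were higher and 20 lower (3 and 22 adjusted over the list alone; median −0.61, adjusted p 1.77e-05, 0.204 estimated), with H4C3, a core histone, 4.18-fold lower (−2.06 ± 0.32). Of 17 snoRNA host genes 0 were higher and 9 lower (0 and 11 adjusted over the list alone; median −1.04, adjusted p 0.000128, 0.204 estimated), with SNHG5 3.94-fold lower (−1.98 ± 0.35). Of 6 structured small RNAs 0 were higher and 5 lower (0 and 5 adjusted over the list alone; median −2.36, adjusted p 0.000128, 0.202 estimated). Of 55 snoRNAs and scaRNAs 0 were higher and 7 lower, also over the list alone (median −0.57, adjusted p 0.0219, 0.483 estimated). Of 14 nuclear-retained long non-coding RNAs 0 were higher and 3 lower (0 and 5 adjusted over the list alone; median −0.88, adjusted p 0.0176, 0.358 estimated). The list held SLC7A2, which was counted on a protein coding transcript, and the 13 others had a median of −0.92 (adjusted p 0.0238, 0.395 estimated). Among them was OIP5-AS1, which buffers an mRNA-binding protein, 3.09-fold lower (−1.63 ± 0.26). NEAT1 did not pass (log2 −1.51 ± 0.55, adjusted p 0.0605), but passed without the MDA-MB-231 culture (−0.52, adjusted p 0.0074), with total counts (0.0455), no filter (0.021), a mean count of 50 (0.0496) and the DESeq2 Wald test (0.0202). Without an MCF-7 culture RPS13 passed (adjusted p 0.0244 to 0.0329), SNHG5 and OIP5-AS1 did not (0.084 to 0.111), COX6C did not without the vehicle culture (0.0651) and H4C3 did not without the E2 culture (0.091). Without the MDA-MB-231 culture the lists of nuclear-retained RNAs and of snoRNAs did not pass (0.107 and 0.114).

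The other lists did not pass the camera test for PSF. Of 11 circadian clock genes 3 were higher and 0 lower, also over the list alone (median 0.39, adjusted p 0.124), with PER2 3.07-fold and PER1 2.85-fold higher (1.62 ± 0.27 and 1.51 ± 0.28). Their calls and that of CUL1 were lost without either MCF-7 culture, where 0 genes passed upward. Of 488 zinc finger genes 28 were higher and 41 lower (8 and 16 adjusted over the list alone; median −0.12, adjusted p 0.182). Of 22 luminal markers 6 were higher and 4 lower (6 and 5 adjusted over the list alone; median 0.20, adjusted p 0.379), and of 10 genes of the SCF ligase and its substrates 1 was higher and 4 lower (median −0.05, adjusted p 0.393), with CUL1, the scaffold of the ligase, 2.1-fold higher (1.07 ± 0.20). Of 29 estrogen-induced genes 6 were higher and 5 lower (median −0.13, adjusted p 0.814), and of 14 estrogen-repressed genes 3 were higher and 1 lower (median −0.03, mean 0.12, tested upward, adjusted p 0.814). Mesenchymal markers had a median of 0.05 and a mean of −0.13 and were tested downward (1 of 22 higher and 2 lower, adjusted p 0.745). The list of bait protein mRNAs also held PSPC1, which no antibody here targeted. PSPC1 was the 1 of 3 called higher, and the list did not pass (median 1.43, adjusted p 0.172). Without the MDA-MB-231 culture this list passed in camera (median 2.74, adjusted p 0.000246). Markers of blood, fibroblasts and liver did not pass (1 of 5 higher, median 1.02, adjusted p 0.164). The 4 study genes, possibly chosen on these libraries and so not independent evidence, had 0 higher and 1 lower, also over the list alone, with a median of 0.01 and a test downward (adjusted p 0.814).

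**Figure D3:**
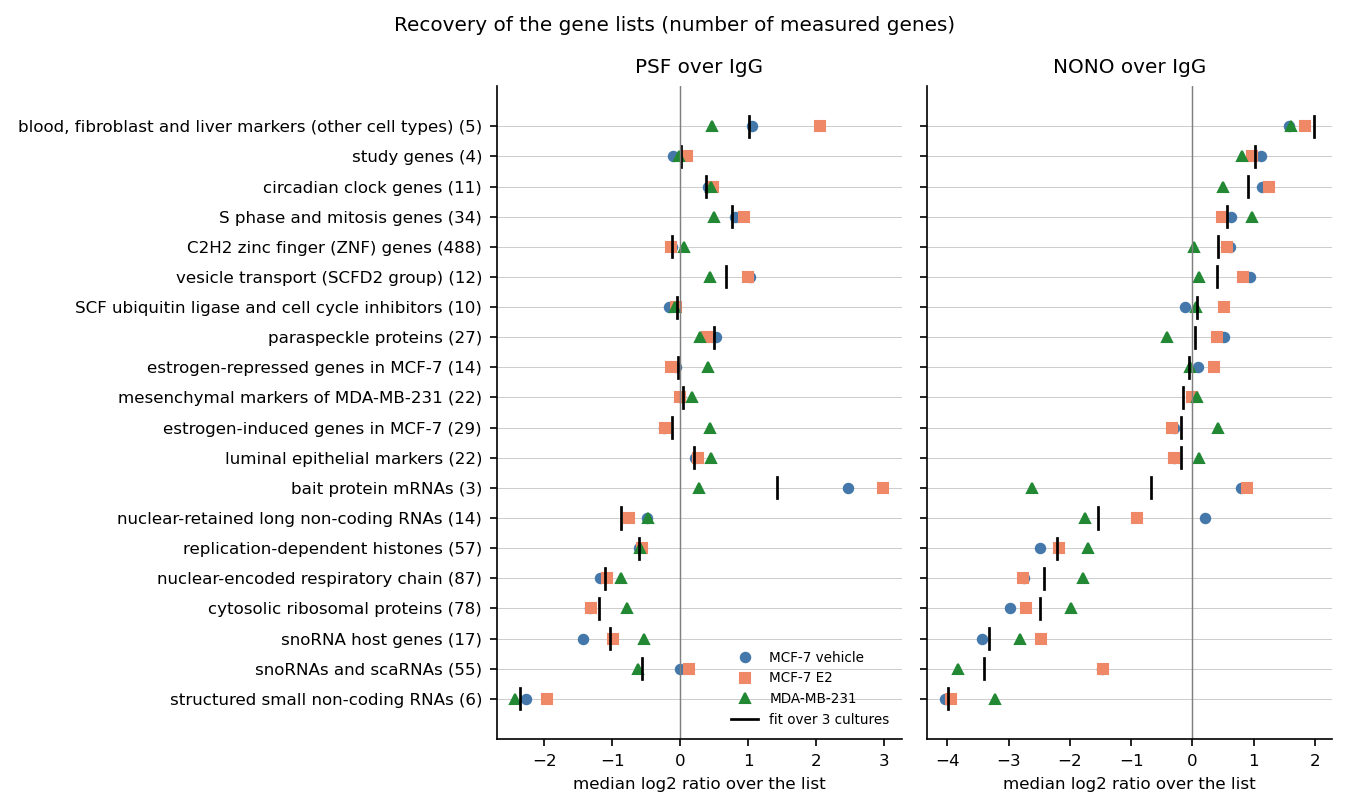
The panels plot the median log2 ratio of PSF over IgG and of NONO over IgG for each of the 20 lists, with a symbol per culture and a black line for the fit over 3 cultures. Ribosomal protein genes had a median of −1.19 with PSF and −2.49 with NONO.

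NONO against IgG asked the same for NONO. IARS1 (NM_013417, chromosome 9, 94972490 to 95056038), the isoleucine tRNA ligase, was recovered 9.50-fold more than with IgG (log2 3.25 ± 0.25, adjusted p 3.15e-06). CLTC (NM_001288653, chromosome 17, 57697050 to 57774317), the clathrin heavy chain of coated vesicles, was recovered 9.20-fold more (3.20 ± 0.26). UTP20 (NM_014503, chromosome 12, 101673905 to 101780397), a ribosome assembly factor, was recovered 10.3-fold more (3.37 ± 0.31), and ACSL1 (NM_001995, chromosome 4, 185676749 to 185747268), which activates fatty acids, 10.2-fold more (3.35 ± 0.33). HERC5, an interferon-induced ligase, and TGFBR3, a growth factor receptor, were recovered 9.07-fold and 8.76-fold more (3.18 ± 0.44 and 3.13 ± 0.47). RCBTB2, NYNRIN and CNTNAP4 had at most 3 IgG counts, and their pooled ratios were 19.3 (6.51 to 94.6), 17.8 (4.83 to 149) and 14.7 (3.94 to 123). The CNTNAP4 call was lost without the vehicle or the E2 culture (0.0525 and 0.0899). That of NYNRIN was lost without the E2 culture (0.0548) and with input as the control (1.34, adjusted p 0.191). PCOLCE2 had 42 NONO counts, 35 of them in MDA-MB-231, and 0 IgG counts, at least 1.49-fold more. It lost its call without the MDA-MB-231 IgG library (adjusted p 0.194) and with input as the control (0.33, adjusted p 0.725).

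RPPH1 was 61.2-fold lower with NONO (log2 −5.93 ± 0.33, adjusted p 1.58e-06), SNORD133 80.6-fold (−6.33 ± 0.39) and RN7SL3 70.2-fold (−6.13 ± 0.48). MT-RNR2, a ribosomal RNA of mitochondria, was 61.1-fold lower (−5.93 ± 0.56), and LINC01011 had 12 IgG counts and 0 NONO counts, at least 4.18-fold lower. MALAT1 (NR_002819, chromosome 11, 65265209 to 65273983) was 20.1-fold lower (−4.33 ± 0.76, adjusted p 0.000474) and NEAT1 (NR_131012, chromosome 11, 65190269 to 65213009) 10.3-fold lower (−3.37 ± 0.60, adjusted p 0.000514). Without the MDA-MB-231 culture they stood at −3.02 and −2.1, and the IgG library of that culture held them 7.71-fold and 7.53-fold over input. Of 13832 genes, 3818 were higher and 3806 lower with NONO, 8415 had an unadjusted edgeR p under 0.05, and 6768 of the called genes had the same sign in all 3 cultures. Over 4-fold, 686 genes were higher and 1721 lower. Without the vehicle culture 2335 genes were higher, and without the E2 culture 2238.

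Among the study genes, SKP2 was 2.06-fold higher with NONO (log2 1.04 ± 0.27, adjusted p 0.00535) and E2F8 2.06-fold higher (1.04 ± 0.25, adjusted p 0.00334). ESR1 was 1.99-fold higher (0.99 ± 0.33, adjusted p 0.0237), with 1.10 and 1.09 in the MCF-7 cultures and 1 IgG count against 0 NONO counts in MDA-MB-231. The ESR1 call was lost without any one of the 6 MCF-7 IgG, PSF and NONO libraries (adjusted p 0.0553 to 0.178). Without the E2 culture SKP2 had an adjusted p of 0.0685 and E2F8 of 0.118, and without the vehicle culture E2F8 had 0.0939. SCFD2 did not pass (0.89 ± 0.42, adjusted p 0.0873), except without the MDA-MB-231 culture (0.97, adjusted p 0.0279). SFPQ had −0.68 ± 0.63 (adjusted p 0.377), with −2.65 in MDA-MB-231, 0.79 in MCF-7 given vehicle and 0.89 in MCF-7 given E2, and its sign turned without the MDA-MB-231 culture (0.76). PSPC1 had 0.22 ± 0.53 (adjusted p 0.744) and passed without the MDA-MB-231 IgG library (1.43, adjusted p 0.00142). NONO mRNA (NM_001145408, chromosome X, 70503042 to 70521018) had −0.86 ± 0.49 (adjusted p 0.152).

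Among the lists, genes of S phase and mitosis, the clock and zinc fingers passed upward with NONO in camera at the preset correlation. Among random lists matched on expression and transcript length they lay at percentiles 97.1, 85.2 and 99.99, and the first 2 of these lay within the 95% range of the random lists. Of 34 genes of S phase and mitosis 14 were higher and 2 lower, also over the list alone (median 0.56, camera adjusted p 0.0177, 0.533 with estimated correlation). MCM6 (NM_005915, chromosome 2, 136597196 to 136634047), a replication helicase subunit, was 7.36-fold higher (log2 2.88 ± 0.28), TOP2A 5.38-fold (2.43 ± 0.51) and CDC25A, a phosphatase that starts S phase, 5.85-fold (2.55 ± 0.28). Of 11 clock genes 6 were higher and 1 lower, also over the list alone (median 0.91, adjusted p 0.0486, 0.368 estimated), with NR1D2 (NR_110524, chromosome 3, 23986751 to 24022109), a clock repressor, 8.59-fold higher (3.10 ± 0.20) and BMAL1, a clock activator, 4.12-fold (2.04 ± 0.42). Of 488 zinc finger genes 157 were higher and 58 lower (149 and 56 adjusted over the list alone; median 0.41, adjusted p 0.0229, 0.717 estimated). Without the MDA-MB-231 culture 0 lists passed upward in camera, and without either MCF-7 culture 1 did. Without MDA-MB-231 the adjusted p was 0.228 for S phase and mitosis, 0.064 for the clock and 0.0561 for zinc fingers.

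Short mRNAs and small RNAs were lower with NONO. Of 78 ribosomal protein genes 1 was higher and 70 lower (1 and 71 adjusted over the list alone; median −2.49, adjusted p 1.45e-24, 0.146 estimated), with RPS12, of the small subunit, 48.1-fold lower (−5.59 ± 0.37). Of 87 respiratory chain genes 4 were higher and 69 lower, also over the list alone (median −2.42, adjusted p 2.26e-19, 0.168 estimated), with COX7A2, a cytochrome oxidase subunit, 24.0-fold lower (−4.59 ± 0.32). Of 57 histone genes 0 were higher and 54 lower, also over the list alone (median −2.22, adjusted p 6.89e-16, 0.155 estimated), with H4C1 9.27-fold lower (−3.21 ± 0.37). Of 17 snoRNA host genes 15 were lower, also over the list alone (median −3.33, adjusted p 6.10e-08, 0.146 estimated), with SNHG6 23.9-fold lower (−4.58 ± 0.45). Of 55 snoRNAs and scaRNAs 3 were higher and 45 lower (3 and 46 adjusted over the list alone; median −3.41, adjusted p 1.76e-06, 0.368 estimated), with SCARNA2, which guides changes to spliceosomal RNA, 44.2-fold lower (−5.47 ± 0.34), and this list did not pass without MDA-MB-231 (0.146). The 6 structured small RNAs were all lower, also over the list alone (median −4.0, adjusted p 0.000215, 0.155 estimated), with RMRP, the RNA of ribonuclease MRP, 20.2-fold lower (−4.33 ± 0.66).

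The other lists did not pass the camera test for NONO. The list of nuclear-retained long non-coding RNAs had 3 of 14 higher and 8 lower (median −1.54, adjusted p 0.422, with a median of 0.06 without the MDA-MB-231 culture), and paraspeckle protein genes 7 of 27 higher and 1 lower (median 0.04, adjusted p 0.607), with HNRNPK, an RNA-binding protein, 2.19-fold higher (1.13 ± 0.22), a call lost without either MCF-7 culture (0.0556 to 0.0601). Vesicle transport genes had 4 of 12 higher and 3 lower (median 0.40, adjusted p 0.479), with VPS45, which acts in endosome fusion, 3.27-fold higher (1.71 ± 0.24). Without SLC7A2, counted on a protein coding transcript, the first list had 2 of 13 higher and 8 lower (median −1.58, adjusted p 0.215). The medians of its 14 members were −1.76 in MDA-MB-231, 0.21 in MCF-7 given vehicle and −0.90 in MCF-7 given E2. The SCF ligase list had 3 of 10 higher and 4 lower, with a median of 0.07, a mean of −0.39 and a test downward (adjusted p 0.905). CUL1 was 3.09-fold higher (1.63 ± 0.20) and RBX1, its short partner mRNA, 11.2-fold lower (−3.48 ± 0.37). Estrogen-induced genes had 4 of 29 higher and 8 lower (median −0.18, adjusted p 0.607), and estrogen-repressed genes 4 of 14 higher and 4 lower (median −0.06, adjusted p 0.959). Luminal markers had 5 of 22 higher and 7 lower (median −0.19, adjusted p 0.607), and mesenchymal markers 5 of 22 higher and 4 lower, with a median of −0.16, or 1.20 without the MDA-MB-231 culture, and a test upward (adjusted p 0.969). Markers of blood, fibroblasts and liver had 3 of 5 higher (median 1.98, adjusted p 0.234), bait protein mRNAs 0 of 3 (median −0.68, adjusted p 0.905), and study genes, possibly chosen on these libraries and so not independent evidence, 3 of 4 over all genes and over the list alone (median 1.02, adjusted p 0.172).

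Recovery followed the length of the mRNA. Coding transcripts under 1000 bases had a median log2 ratio of −2.53 with NONO (560 genes), and those of at least 8000 bases had 1.25 (881 genes). With PSF these medians were −0.98 and 0.55. Across 12706 coding genes, which are not independent replicates, the Spearman correlation of transcript length with recovery over IgG was 0.600 for NONO and 0.319 for PSF. The length of the coding part, known for 11791 genes, gave 0.567 for NONO and 0.644 for PSF. GC content gave −0.283 for NONO and 0.229 for PSF. IgG over input gave 0.221 with transcript length.

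**Figure D4:**
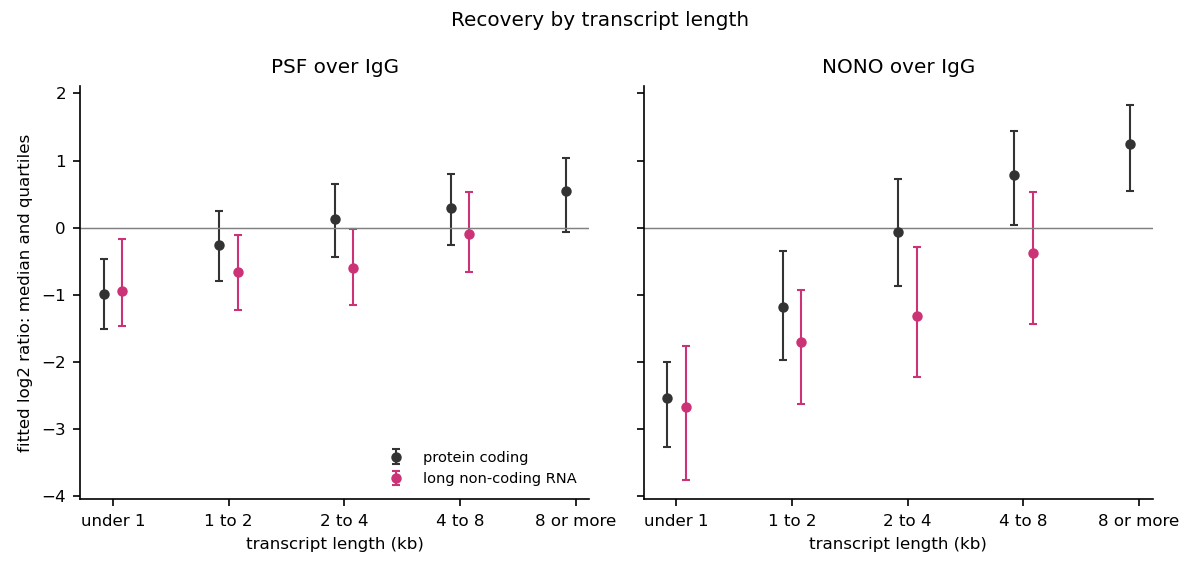
The panels plot the fitted log2 ratio of PSF over IgG and of NONO over IgG (points are medians, bars quartiles) against transcript length in kilobases, for protein coding and long non-coding genes. The NONO median of coding genes went from −2.53 in the shortest bin to 1.25 in the longest.

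PSF against NONO asked which RNAs were recovered unequally with the antibodies. MALAT1 was higher with PSF than with NONO (log2 5.61 ± 0.78, adjusted p 0.000123). STAG3L5P (NR_103720, chromosome 7, 99933702 to 99938951), a cohesin pseudogene, was 76.7-fold higher with PSF (6.26 ± 0.78, adjusted p 6.06e-05), and MNS1, a cilium protein, 70.8-fold (6.15 ± 1.04). FRG1JP and ZMAT1 had 194 and 208 PSF counts against 1 NONO count each, ratios of 197 (34.9 to 7818) and 211 (37.5 to 8380), and FAM218A had 83 against 0, at least 9.36-fold. MDA-MB-231 held 183, 199 and 79 of these PSF counts, so the pooled ratios describe mostly that culture. FAM218A lost its call without the MDA-MB-231 NONO library (3.51, adjusted p 0.0634). PLEKHF2 (NM_024613, chromosome 8, 96145949 to 96168913), an endosome protein, was 15.5-fold lower with PSF than with NONO (−3.95 ± 0.22, adjusted p 1.86e-06). NEK7 (NM_133494, chromosome 1, 198126108 to 198291548), a mitotic kinase, was 13.7-fold lower (−3.78 ± 0.22), and C6orf120, MAP2K6 and COMMD8 were 13.1-fold, 13.1-fold and 12.4-fold lower.

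SFPQ mRNA was 4.29-fold higher with PSF than with NONO (log2 2.1 ± 0.59, adjusted p 0.0109). NONO mRNA was 2.67-fold higher (1.42 ± 0.48, adjusted p 0.0275), a call lost without the NONO or the PSF library of MDA-MB-231 (adjusted p 0.0771 to 0.104), with counts summed over transcripts (0.0553) or with 6 libraries (0.0664). PSPC1 was 2.61-fold higher (1.39 ± 0.50, adjusted p 0.0344), a call lost without any one of 4 libraries or with summed counts (0.0752). SKP2 was 4.05-fold lower with PSF (−2.02 ± 0.27, adjusted p 8.75e-05). ESR1 was 2.39-fold lower (−1.25 ± 0.33, adjusted p 0.00778) and E2F8 1.70-fold lower (−0.76 ± 0.23, adjusted p 0.0153), and these calls were lost without any one of the 4 MCF-7 PSF and NONO libraries (adjusted p 0.0679 to 0.110). The ESR1 call was also lost with summed counts (0.188) and that of E2F8 with total counts (0.0654). SCFD2 did not pass (0.10 ± 0.38, adjusted p 0.850). Of 13832 genes 3747 were higher with PSF and 3297 with NONO, and 7913 had an unadjusted edgeR p under 0.05. Without the vehicle culture 2189 were higher and 1813 lower with PSF, and without the E2 culture 2232 and 1726.

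Comparisons with input asked which RNAs were recovered beyond their level in the lysate. SFPQ was higher with PSF than in input (log2 2.34 ± 0.61, adjusted p 0.00838), as were TOP2A (2.45 ± 0.50) and MKI67 (2.77 ± 0.51), a marker of dividing cells. MALAT1 was higher with PSF (1.82 ± 0.67, adjusted p 0.0429), a call lost without any one of 8 libraries, with DESeq2 size factors (0.0507), a mean count of 50 (0.0584) or summed counts (0.0593), and lower with NONO (−3.79 ± 0.71, adjusted p 0.000673). NR1D2 and MCM6 were higher with NONO (2.5 ± 0.20 and 2.29 ± 0.28). NEAT1, the RNA of paraspeckles, was not enriched over input with NONO in any culture and lay near input with PSF. Its log2 ratios with PSF were 0.34 in MDA-MB-231, 0.01 in MCF-7 given vehicle and −0.29 in MCF-7 given E2. With NONO they were −2.56, −1.76 and −1.56 in the same order. RPPH1 was lower than input with PSF, NONO and IgG (−6.07 ± 0.34, −7.92 ± 0.37 and −1.99 ± 0.28). With PSF 3365 genes were higher than input and 2561 lower, with NONO 4192 and 3386, and with IgG 56 and 31, with 7019, 8246 and 2732 at an unadjusted edgeR p under 0.05. For IgG over input 2127 genes were higher and 1890 lower without the MDA-MB-231 culture, and at most 4 were higher and 1 lower without any one of the MCF-7 libraries or the MDA-MB-231 input. Without the IgG, NONO or PSF library of MDA-MB-231 271, 288 and 195 were higher and 100, 171 and 131 lower, so the IgG call of RPPH1 depended on single libraries. It was also lost with total counts (0.0502), summed counts (0.0604) and 6 libraries (0.279). Without the vehicle culture 1416 genes were higher and 1317 lower than input with PSF, and without the E2 culture 1515 and 1211. With NONO 2588 and 2395 were higher in these fits. Scaling by total counts moved the median log2 change of all genes from 0.15 to 0.26 for PSF over input, from 0.06 to 0.18 for IgG over input, from −0.02 to −0.12 for NONO over IgG and from 0.14 to 0.24 for PSF over NONO.

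E2 against vehicle in the MCF-7 input asked which mRNAs differed with estrogen, read from 1 library each without a test. EGR3 (NM_004430, chromosome 8, 22545174 to 22550815), an early transcription factor, was 14.6-fold higher with E2 (95% counting interval 7.50 to 32.7). PTGES (NM_004878, chromosome 9, 132500615 to 132515344), a prostaglandin synthase, was 12.3-fold higher (7.53 to 21.5), and PGR (NM_000926, chromosome 11, 100900355 to 101000544), the progesterone receptor, 8.46-fold (5.53 to 13.5). MYBL1, a transcription factor, was 11.9-fold higher (5.79 to 28.2) and CXCL12, a chemokine, 10.8-fold (4.37 to 34.6). C1QTNF6, PITPNM2, RBM24, INSYN1 and JAK2 were 8.32-fold to 5.37-fold higher. GREB1, a growth regulator bound by the receptor, was 3.83-fold higher (3.45 to 4.27), CCND1, the cyclin of G1, 2.11-fold (1.97 to 2.26), TFF1, a secreted peptide, 1.67-fold (1.57 to 1.79) and MYC 1.41-fold (1.17 to 1.69). BMF (NM_001003940, chromosome 15, 40380092 to 40401075), which promotes cell death, was 3.57-fold lower (ratio 0.280, 0.156 to 0.480). ST8SIA4, TGFB3, ZSWIM5, NFKBIZ, DCAF4, PTPN14, ID3, GAREM1 and BCL3 were 3.13-fold to 2.40-fold lower.

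The 4 fractions of a culture are not independent measurements of the response. Of 5782 genes with 50 counts in an input library, 2208 had the same direction in all 4 fractions (38.2%), 1139 of them higher and 1069 lower. Among these, 121 were over 2-fold higher and 25 over 2-fold lower in input. All 26 estrogen-induced genes with enough counts were higher in all 4 fractions, with a median of 1.20 at percentile 100 of random lists. All 8 estrogen-repressed genes were lower in all 4, with a median of −0.70 at percentile 0. Of 13 S phase and mitosis genes 7 were higher and 6 lower. ESR1 had a ratio of 0.753 (0.667 to 0.849), NONO of 0.777 (0.688 to 0.878), PSPC1 of 0.499 (0.310 to 0.790) and SFPQ of 0.867 (0.683 to 1.10). PSPC1 over input was 2.85-fold with vehicle and 5.65-fold with E2 in PSF, and 1.26-fold and 2.26-fold in NONO. Its drop in input was thus hardly seen in these fractions. In IgG it was 0.516-fold and 0.631-fold over input, so most of the drop was seen there. SKP2 and E2F8 had 0.624 (0.361 to 1.06) and 0.677 (0.325 to 1.38), differences not detectable at this depth. SCFD2 had 12 counts with vehicle and 2 with E2, a ratio of 0.158 (0.0172 to 0.710), while its log2 ratio was 0.51 in IgG, −0.05 in PSF and −0.08 in NONO.

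**Figure D5:**
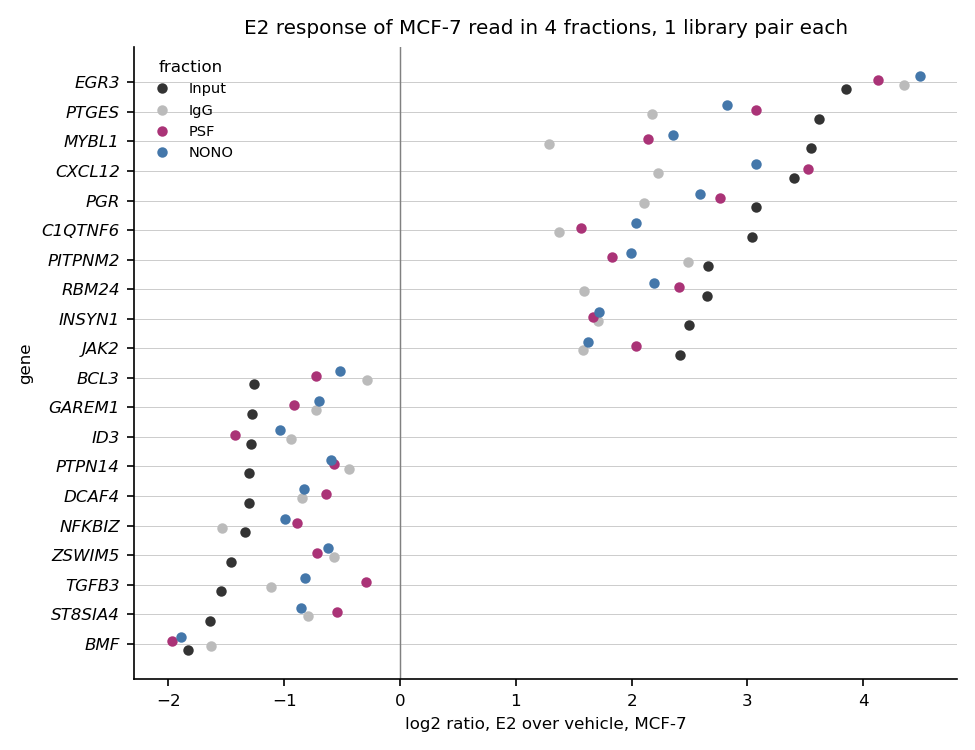
The plot gives the log2 ratio of E2 over vehicle (x axis) for the 10 highest and 10 lowest genes in MCF-7 (y axis), with a point per fraction from 1 pair of libraries each. EGR3 was highest in input (14.6-fold) and BMF lowest (3.57-fold lower). The genes were chosen for the same direction in all 4 fractions.

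The difference in recovery under E2 asked whether recovery with PSF or NONO beyond the IgG background differed with the hormone, again without a test. Among 2037 genes for PSF the difference had an SD of 0.352 and 9 exceeded 2-fold, and among 3719 for NONO the SD was 0.307 and 6 exceeded 2-fold. ALG8, a glycosylation enzyme, had the highest PSF difference (1.28 log2), followed by the ribosomal RPL10 (1.27), RPL27 (1.23) and RPL27A (1.05) and by CSTA (1.02). RPSA (−1.45), SPRYD4 (−1.26), RPS29 (−1.12), JUN (−1.01) and ANAPC2 (−1.0) had the lowest. For NONO the highest were RPLP2 (1.06), RPL10 (1.06), MT2A (0.94), MT-CO2 (0.93) and H2BC7 (0.93), and the lowest RPS29 (−1.48), ALDH9A1 (−1.11), ANKRD13D (−1.04), SKIC2 (−1.01) and ZFP91-CNTF (−0.98). The IgG libraries themselves differed for RPL10 (−1.21) and RPSA (1.63), and with input as the control their PSF differences were 0.33 and 0.07, against 1.14 for ALG8. With this control RPL27 stood at 0.97, RPL27A at 0.31, CSTA at 0.53, SPRYD4 at −1.05, RPS29 at −0.07, JUN at −0.30 and ANAPC2 at 0.65 for PSF. For NONO RPLP2 stood at 0.12, RPL10 at 0.12, MT2A at 0.09, MT-CO2 at 0.07, H2BC7 at 0.57, RPS29 at −0.43, ALDH9A1 at −0.16, ANKRD13D at −1.08, SKIC2 at −0.22 and ZFP91-CNTF at −0.11. ESR1 had a difference of 0.03 with PSF and −0.01 with NONO, SKP2 0.18 and 0.22, E2F8 0.38 and 0.14, and SCFD2 −0.56 and −0.60. With input as the control SCFD2, which had 2 input counts with E2, turned to 2.54 with PSF and 2.5 with NONO.

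MDA-MB-231 against MCF-7 given vehicle, in input, asked how the estrogen receptor negative line differed from the positive one, without a test. VIM (NM_003380, chromosome 10, 17270209 to 17279596), the filament of mesenchymal cells, had 9362 counts in MDA-MB-231 and 2 in MCF-7. PLAT (NM_000930, chromosome 8, 42032236 to 42065242), a plasminogen activator, was at least 270-fold higher in MDA-MB-231, and FOSL1, a transcription factor of invasion, at least 190-fold. CNN3, CDC42EP3 and CD74 were at least 190-fold, 164-fold and 160-fold higher. TFF1 (NM_003225, chromosome 21, 43782391 to 43786644) was at least 1125-fold higher in MCF-7, CDH1 (NM_001317185, chromosome 16, 68771193 to 68869445), the adhesion protein of epithelia, at least 718-fold and ESR1 at least 489-fold. DSCAM-AS1, SULF2 and BMP7 were at least 831-fold, 759-fold and 502-fold higher in MCF-7. NEAT1 was 16.3-fold higher in MDA-MB-231 (12.7 to 21.1), E2F7, a partner of E2F8, 34.5-fold (20.1 to 65.1), FUS 5.15-fold (3.96 to 6.82) and SFPQ 2.01-fold (1.69 to 2.42). SCFD2, SKP2 and E2F8 had ratios of 1.51 (0.781 to 3.14), 0.863 (0.579 to 1.31) and 1.14 (0.681 to 1.98), differences not detectable at this depth.

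List medians differed between the lines. The mesenchymal list holds markers of MDA-MB-231, so its direction was largely set by the choice of list. All 21 members that entered were higher in MDA-MB-231 (median 8.13, percentile 100). Only 1 member of this list had 50 counts in an MCF-7 input library, so most entered through their MDA-MB-231 counts. Its direction and percentile are therefore no independent evidence of a difference between the lines. Of 19 luminal markers 17 were lower in MDA-MB-231 (median −4.71, percentile 0). Of 30 S phase and mitosis genes 28 were higher in MDA-MB-231 (median 1.5, percentile 100), and 17 of 21 estrogen-induced genes were lower (median −2.58, percentile 0). Of 10 estrogen-repressed genes 8 were also lower (median −1.30, percentile 0.09). Ribosomal protein genes had a median of −1.17 and respiratory chain genes of −0.64, both at percentile 0.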

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

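Both tests of carry-over of PSF material and the test of nuclear RNA bound by the control antibody were chosen after the result was seen.

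The ratios of the single MDA-MB-231 libraries lay apart from those of the MCF-7 cultures for many RNAs, by a term for cell line in edgeR at an adjusted p under 0.05. MDA-MB-231 had 1 library per fraction and the spread came from the MCF-7 cultures, so a library that stood out could not be told from a cell line that did. The values below describe these libraries and are not a test of the lines. The mitotic mRNAs named for PSF had lower ratios in the MDA-MB-231 libraries. The log2 ratio of PSF over IgG in MDA-MB-231 minus that in MCF-7 was −2.95 for TOP2A, −2.79 for CENPE, −2.81 for HMMR, −3.04 for TPX2, −1.93 for MKI67, −1.69 for PLK1 and −0.88 for MCM10. It was −2.45 for SPTAN1, −2.72 for SFPQ, −2.49 for PSPC1, −0.57 for NONO mRNA, −0.89 for FUS and −0.89 for PER1. For SCFD2 it was −1.39, and the other study genes did not pass. The ratio was also lower in MDA-MB-231, by −2.0 for RN7SL3, −0.57 for RPPH1, −2.54 for RMRP and −2.07 for NEAT1, and COX6C by −1.10. It was higher for RPS13 (0.92) and for the non-coding DANCR (1.37) and OIP5-AS1 (0.97). Over all genes 1991 had a higher and 1616 a lower PSF ratio in MDA-MB-231.

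For NONO over IgG the difference was −3.48 for SFPQ, −2.64 for NONO mRNA, −3.04 for PSPC1, −3.47 for MALAT1 and −3.44 for NEAT1. It was −2.47 for TOP2A, −1.36 for BUB1, a mitotic checkpoint kinase, −1.84 for BMAL1, −1.04 for UTP20, −2.30 for SNHG6 and −2.13 for RN7SL3. SKP2 (0.90), RPS21 (1.57) and RPL29 (1.27) had higher ratios in MDA-MB-231. Over all genes 2904 were higher and 2751 lower.

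Differences were fewer when NONO was set against input. There 204 genes had a higher and 177 a lower ratio in MDA-MB-231, against 2042 and 1295 for PSF over input and 1862 and 1908 for IgG over input. IgG over input differed by 3.36 for SFPQ, 2.55 for NEAT1 and −0.42 for RPPH1. PSF over input differed by 0.63 for SFPQ, 2.08 for MALAT1, 0.84 for MKI67, −0.80 for TOP2A and −0.99 for RPPH1. PSF over NONO had 2964 higher and 2547 lower, with SCFD2 at −1.17, SFPQ at 0.76, NONO mRNA at 2.07 and PSPC1 at 0.55.

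The IgG library of MDA-MB-231 held RNAs that PSF recovers. SFPQ was 6.84-fold over input there and 0.760-fold in MCF-7 given vehicle, and across 13046 genes the library had a Pearson correlation of 0.960 with MDA-MB-231 PSF and 0.921 with input. Swapped IgG and PSF labels were argued against, since the correlation with the MCF-7 PSF profile was 0.471 for the IgG library and 0.689 for the PSF library, a difference of −0.22. Carry-over of PSF material as the only addition to an input-like background was argued against for nuclear-retained RNAs. Of the 7 that were over 2-fold above input, 6 lay above the PSF library too, among them NEAT1 by 2.57 log2, JPX by 2.98 and KCNQ1OT1 by 1.92. The exception was MALAT1, which lay below PSF (−0.46). Carry-over beside another background was not excluded. For other genes carry-over could not be decided, as 46 of 9230 lay 2-fold above both input and PSF, against 65 of 6656 and 99 of 6815 in the MCF-7 IgG libraries. The data are consistent with more nuclear RNA bound by the control antibody in MDA-MB-231, where the median of the 14 members of the nuclear-retained list over input was 1.09 against −0.06 and 0.13 in MCF-7, or 1.40 against −0.10 and 0.19 without the protein coding SLC7A2, and a difference between the lines or in washing was not tested.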

How the results depend on the processing

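The fits without 1 library, every alternative for the comparisons with input, the lists without the MDA-MB-231 IgG library and the nuclear-retained list without SLC7A2 were chosen after the data were seen. A term for culture in every tested fit paired the fractions of a culture. No paired analysis was possible because each culture and fraction had 1 library for E2 against vehicle and for the lines. A pseudocount of 0.1 and a filter on low values for normalized units were not run, since the files hold counts. In fits without a culture, its removal leaves fewer libraries, and the cause of the other changes was not tested.

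RPPH1, RN7SL3 and SNORD133 were lower with PSF and with NONO than with IgG, past the threshold, in every alternative fitted. With DESeq2 size factors 185 of 188 named gene results kept their direction and side of the threshold, and with the DESeq2 Wald test 142 of 145. Counts of genes for PSF over IgG stayed between 1478 and 2262 higher and between 1422 and 1958 lower when scaling, filter, test, transcript choice or the number of libraries changed. For NONO over IgG the higher genes stayed between 2761 and 4008. NONO over IgG had 2524 lower genes when only the 6 libraries of its fractions were fitted.

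With input as the control, 3365 genes were higher and 2561 lower with PSF, and 4192 and 3386 with NONO. ESR1 turned to 0.0472, E2F8 to −0.0848 and NEAT1 to 0.0237 for PSF, and SFPQ turned to 0.24 for NONO. The calls of COL28A1 (adjusted p 0.11) and FAM184B (0.254) for PSF and of PCOLCE2 (0.725), NYNRIN (0.191) and NUDT21 (0.231) for NONO were lost. With input as the control, 4 genes differed over 2-fold in PSF recovery under E2.

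SCFD2 in PSF over NONO turned to −0.0164 with 6 libraries. ESR1 in PSF over input turned to −0.0228 with DESeq2 size factors, −0.0627 with a mean count of 50, −0.0825 with the DESeq2 Wald test and −0.0354 with 6 libraries, and E2F8 turned to 0.0195 with total counts. With a mean count of 50, PSPC1 in NONO over IgG turned to −0.0015. NONO over IgG lost the ESR1 call with total counts (adjusted p 0.062), a mean count of 50 (0.0663), counts summed over transcripts (0.325) and 6 libraries (0.117). SFPQ in PSF over IgG passed with no filter (0.0492) and with 6 libraries (0.0206).

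For IgG over input, total counts gave 13 higher and 1 lower, no filter beyond 1 count 89 and 62, a mean count of 50 100 and 62, and the DESeq2 Wald test 449 and 429. Counts summed over transcripts gave 0 and 0, as did the fit of 6 libraries, in edgeR. With estimated correlation 0 lists passed upward and 0 downward for PSF, and 0 and 0 for NONO, in camera.

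Leaving out 1 culture or 1 library gave 0 to 3832 higher and 37 to 3714 lower genes for PSF over IgG. The same fits gave 2238 to 4605 higher for NONO over IgG, 2189 to 5002 higher and 1726 to 4261 lower for PSF over NONO, 1416 to 4135 higher and 1211 to 3837 lower for PSF over input, and 2395 to 4666 higher for NONO over input. For IgG over input they gave 0 to 2127 higher and 0 to 1890 lower, the highest of each being without the MDA-MB-231 culture. Without 1 culture, SFPQ in NONO over IgG ranged from −1.44 to 0.76, PSPC1 from −0.49 to 1.47, and SCFD2 in PSF over NONO from −0.0808 to 0.52. ESR1 in PSF over input ranged from −0.0719 to 0.31. In IgG over input SFPQ ranged from −0.59 to 1.58, SCFD2 from −0.26 to 0.56 and SKP2 from −0.32 to 0.0059.

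Lists that passed upward for NONO numbered 0 to 3. The median of estrogen-repressed genes ranged from 0.0309 to 0.12 for PSF and from −0.0452 to 0.51 for NONO, and that of bait protein mRNAs from −1.38 to 0.76 for NONO. For NONO that of nuclear-retained RNAs ranged from −1.93 to 0.06, of mesenchymal markers from −0.36 to 1.20, of the SCF ligase list from −0.26 to 0.22 and of paraspeckle genes from −0.13 to 0.32. For PSF that of mesenchymal markers ranged from −0.12 to 0.49 and of estrogen-induced genes from −0.29 to 0.05. Without the vehicle culture 48 named gene results lost their call, without the E2 culture 51, and without MDA-MB-231 1.

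With a pseudocount of 5 the mesenchymal median between lines was 6.21. With a filter of 10 counts, 261 genes were over 2-fold higher and 132 lower with E2, and 110 of 3152 and 191 of 6063 genes differed over 2-fold in recovery with PSF and NONO. The smallest library, the input of MCF-7 given vehicle, held 1570129 counts.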

Other observations

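The test of transcript length alone was chosen after the result was seen.

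SFPQ mRNA was 7.04-fold over input with PSF in MDA-MB-231, 4.46-fold in MCF-7 given vehicle and 4.56-fold in MCF-7 given E2. With IgG it was 6.84-fold, 0.760-fold and 0.572-fold over input, and in MDA-MB-231 PSF and IgG differed by a log2 of 0.04. With NONO it was 1.09-fold and 1.32-fold over input in MDA-MB-231 and MCF-7 given vehicle.

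RNA of the mitochondrial genome differed between the cultures in the PSF libraries. The median log2 over input of its 33 genes, mRNAs and other RNAs together, was 0.01 with PSF and −4.20 with NONO in MDA-MB-231, −4.13 and −5.21 in MCF-7 given vehicle, and −3.77 and −5.09 in MCF-7 given E2. With IgG it was −0.07, −0.85 and −1.25 in these cultures. MT-ND4, a subunit of the respiratory chain, stood at −0.07 with PSF in MDA-MB-231 and at −4.86 in MCF-7 given vehicle. MT-RNR2, the large mitochondrial ribosomal RNA, was below input with PSF in both (−4.72 and −3.05). In the IgG library of MDA-MB-231 MT-ND4 stood at −0.07 and MT-RNR2 at −1.55, a gap in the same direction. Carry-over of PSF material into that library was not decided for these genes, so it does not show the gap without PSF. In the IgG libraries of MCF-7 the gap went the other way. MT-ND4 stood at −1.05 and MT-RNR2 at 0.46 with vehicle, and at −1.74 and −1.55 with E2.

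Longer mRNAs were recovered more with NONO, a pattern that may be technical. A loss confined to short RNAs was argued against by the 7121 coding genes with transcripts over 3000 bases. Among them the Spearman correlation of length with NONO over IgG was still 0.312 (95% bootstrap interval 0.291 to 0.333). The interval covers the sampling of genes and not of libraries. A loss graded with size would also give a correlation above 3000 bases, so it was not tested. The 16 long non-coding RNAs over 8000 bases had a median log2 over input of −0.41 against 1.53 for 881 coding genes of that length. The difference of −1.94 (−3.17 to −1.17) argued against transcript length as the only factor across these classes. It does not test length as the cause of the gradient among coding genes. Among 648 long non-coding RNAs recovery also rose with length (Spearman correlation 0.393 for NONO over IgG and 0.468 for NONO over input). GC content was argued against, with a median correlation of 0.575 within 5 GC groups (0.408 to 0.703). A biological preference for long mRNAs stays a hypothesis found and tested on the same data.

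Matching on length left some list medians outside the 95% range of the random lists and others within it. The random lists drew genes independently, so correlation between members was not covered, and no list passed camera with estimated correlation. Length was matched in 10 bins, so differences in length within a bin remained. The match used transcript length, whereas PSF over IgG correlated more with coding length (Spearman correlation 0.644, against 0.319 with transcript length). Coding length was not matched, so the PSF percentiles can reflect it. Zinc finger genes for PSF did not pass camera at the preset correlation either (adjusted p 0.182). Among random lists matched on expression and transcript length, the S phase and mitosis genes lay at percentile 100 for PSF, zinc finger genes at 0 for PSF and 99.99 for NONO, and ribosomal protein genes at 0 and 0.01. Within the 95% range of the random lists lay the S phase and mitosis genes for NONO (97.1), the clock genes for NONO (85.2), and for PSF the paraspeckle genes (83.8), snoRNAs and scaRNAs (80.0) and snoRNA hosts (3.86). Histones lay within it for PSF (85.0) and NONO (33.1).

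Genes called against IgG overlapped between PSF and NONO. Both ratios rose with transcript length (Spearman correlation 0.319 for PSF and 0.600 for NONO across coding genes). The overlap was not adjusted for length. Of the genes past both tests 1158 were higher with both proteins, among them TOP2A, CLTC and CUL1, where independence gives 517.0, and 1006 were lower with both, among them RPPH1, RPS21 and SNHG5, where independence gives 443.0, and 276 went opposite ways, among them SKP2. The ratios share the 3 IgG libraries, and simulated sets without any effect gave a correlation of 0.597 and a covariance of 0.127, against 0.476 and 0.642 observed. The covariance beyond the simulated one was 0.515. Splitting the IgG libraries between the ratios was not possible with 1 per culture, so shared controls were not excluded as a source of part of the excess. PSF over IgG and NONO over input share no library and had 1382 genes higher and 1054 lower in both, where independence gives 568 and 394, with 208 opposite and a covariance of 0.751. PSF over input and NONO over IgG, which also share none, had 1405 and 1321, where independence gives 929 and 705, with 998 opposite and a covariance of 0.471.

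For each tested comparison 1 of the 10 splits of its libraries into 3 and 3, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The other splits mixed both fractions in a group, so the difference between fractions entered their spread and lowered their counts. Those counts are therefore no level for libraries without an effect. PSF over IgG had 3483 genes against at most 1 in another split, and NONO over IgG had 7624 against 0. PSF over NONO had 7044 against 0, PSF over input 5926 against 0, NONO over input 7578 against 0 and IgG over input 87 against 3, all in edgeR.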
